A study of Homo sapiens with 16 samples.

How the data were processed

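RNA immunoprecipitated with Argonaute 2 (Ago2) was compared with total RNA in 4 established Hodgkin lymphoma cell lines, L1236, L428, L540 and KM-H2. Ago2 is the protein that carries microRNAs to their target transcripts. Ago2-IP is the immunoprecipitated fraction and Ago2-T the total fraction of the same line, per the labels. No mock or control immunoprecipitate is among the samples, so binding to Ago2 cannot be told apart from unspecific recovery. Each line was hybridised on 2 two-colour Agilent arrays with the dyes swapped, so the 8 arrays gave 16 channels. L1236 and L428 shared slide 1, L540 and KM-H2 shared slide 2, and the slides were scanned separately, per the file headers. Per the labels' protocols, RNA was isolated with Trizol and labelled with Cy3 and Cy5 together with spike-in RNA.

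The deposited values are spot intensities. Per the file headers, they were made with Agilent Feature Extraction 10.7.3.1, which subtracted background, corrected spatial trends and normalized the dyes of each array (linear and lowess) to give processed signals. The deposited median spot and background intensities are not normalized. The other columns used hold flags set by the scanner software, deposited as 0 or 1 (well above background, saturated, non-uniform spot, population outlier). In each file, 17 further per-channel columns were not used. The direction of each ratio came from the dyes in the labels.

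The arrays carry 61657 non-control spots. The files name no genes, so probe accessions were matched, without versions, to a RefSeq gene table of assembly GRCh38.p14, which gave a symbol to 8111 probes (7402 distinct symbols). A further 21985 catalogue probes and 28533 custom probes stayed unnamed, and what the custom probes target is not given in the sources used here. The array grid uses another genome build than the table, so no coordinates are given. The 13 probes of XIST and of genes on the Y chromosome were left out, which left 58629 probes. Control spots and spots flagged as non-uniform or outliers were left out, and no non-control spot was flagged as saturated in either fraction.

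The log2 ratio of processed signals, Ago2-IP over Ago2-T, was centred on each array at the median of the probes kept, with no further loess or quantile step. The processed signals already carried the linear and lowess dye normalization of each array. A one-way shift of the immunoprecipitated RNA can thus not be read from the ratios. A ratio is therefore relative to the median probe. A probe was kept if it was well above background in the Ago2-IP channel on all 8 arrays or in the Ago2-T channel on all 8 arrays, which left 16617 probes. The brightest kept probe stood for a gene, giving 16362 features, of which 3880 had a symbol. No label says that the swapped array came from another immunoprecipitation. The 2 arrays of a line were therefore averaged, and the line was the replicate (n = 4). The p-values measure the spread between these 4 lines, each represented by 1 pair of extracts as far as the labels say. The spread of the 2 fractions is paired by line: deviations from the group means correlated at 0.905 to 0.924 across features between the fractions of the same line. These fractions share arrays and spots, which can add to that correlation. The highest correlation with another line was -0.134, but taking off the mean of 4 lines itself pushes such values below 0.

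Ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, Benjamini-Hochberg over 16362 features, threshold 0.05). The fit had 3 residual and 4.97 prior degrees of freedom. The SE is limma's moderated SE. In all, 26 gene lists were fixed before the data were examined, 6 of them published targets of microRNAs compiled from general knowledge of the literature. Lists with at least 5 measured members were tested against the other named genes with camera at an inter-gene correlation of 0.01. They were tested again with an estimated correlation, and both tests had Benjamini-Hochberg adjustment over the lists. With an estimated correlation camera uses only the 3 residual degrees of freedom, while at the preset correlation their number follows that of the genes. The p-values then rise even where members are uncorrelated. The genes named are the 12 highest and 12 lowest that passed the threshold with the same sign on all 8 arrays, then CDKN1B, MYC, AGO2 and DICER1, then up to 4 members of each list with the lowest p. Other list members are given only as examples of a count and were chosen after their values were seen. Counts per line took features at least 2-fold changed on both arrays of a line, with no test. Alternatives covered background correction, normalization, centring, the filter, pairing, dyes, slide, left-out lines, probe choice and the fold tested. The normexp alternatives (offset 50) used the median spot intensities.

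The procedure was tested on simulated data for this comparison, 16362 features with the spread and dye bias of the real arrays. The array-wide offsets were set by hand. Of 50 features changed 4-fold it found 90%, of 50 changed 2-fold 52%, of 50 changed 1.5-fold 10%, and of 50 changed 1.25-fold 0%. The noise model of this simulation was corrected, and its criteria for passing were replaced, after a first version found fewer of the 4-fold changes than it asked for. Of the 88 calls, 8 fell on the 30 members of a simulated gene list with smaller shifts and 4 on unchanged features. The real arrays gave 9013 calls, so the Benjamini-Hochberg adjustment was stricter in the simulation. The shares found therefore do not give the sensitivity on the real arrays. The number of lines limits the precision, and across features the median SE of the log2 ratio was 0.14. Between 35.7% and 43.0% of probes were well above background in the Ago2-IP channel, and between 32.8% and 41.0% in the Ago2-T channel. A planned test of microRNA sites in 3' untranslated regions was not run, because it needs transcript sequences, which were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.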

Results

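Transcripts recovered with Ago2 were profiled in 4 Hodgkin lymphoma cell lines, in a series concerned with miR-24-3p. The aim was to find microRNA targets among messenger and long non-coding RNAs. For each of L1236, L428, L540 and KM-H2, the Ago2 immunoprecipitate (Ago2-IP) was hybridised against total RNA (Ago2-T) on 2 dye-swapped arrays, 8 arrays in all. Ratios are log2 Ago2-IP over Ago2-T of the scanner's processed intensities, centred on the median probe of each array. Values are means over the 4 lines with limma's SE, and the adjusted p is limma's after Benjamini-Hochberg adjustment over 16362 features. The swapped arrays of a line correlated across features at 0.839 to 0.902.

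The named transcripts most enriched in the Ago2 immunoprecipitate included those of BTG2, SOCS1, ZFP36 and SIAH1, higher on all 8 arrays. BTG2, an antiproliferative gene, stood at a log2 ratio of 4.09 ± 0.14 (SE, n = 4, adjusted p = 4.92e-06). SOCS1, an inhibitor of JAK-STAT signalling, stood at 3.64 ± 0.13 (SE, n = 4, adjusted p = 5.19e-06). ZFP36, which binds AU-rich elements and promotes messenger decay, stood at 3.58 ± 0.15 (SE, n = 4), and the ubiquitin ligase gene SIAH1 at 3.57 ± 0.15 (SE, n = 4). The actin regulators CFL2 and WASL reached 4.51 ± 0.23 and 3.98 ± 0.19 (SE, n = 4), for WASL 15.8-fold above the median probe. The 12 highest named genes were completed by the kinase genes PKN2 (3.68) and SGK1 (3.64), PDCD1LG2 (3.60), which encodes a ligand of PD-1, TNFRSF12A (3.55), the AP-1 subunit gene FOSL1 (3.54) and the vesicle SNARE gene VAMP3 (3.46). Of these 12, VAMP3 differed most between lines, from 1.88 in L428 to 4.89 in L540. The total signal was well above background on 2 of 8 arrays for CFL2, 3 for PDCD1LG2, 4 for PKN2 and 6 for FOSL1, so the ratios of these 4 genes rest on a dim denominator and their sizes and ranks are uncertain.

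The named transcripts with the lowest ratios included those of GNRH2, UCP3 and FHL1, lower on all 8 arrays. GNRH2, which encodes a releasing-hormone peptide, stood at -2.76 ± 0.29 (SE, n = 4, adjusted p = 0.000168), 6.77-fold below the median probe. UCP3, a mitochondrial carrier gene of muscle, stood at -2.39 ± 0.14 (SE, n = 4) and FHL1, a LIM-domain gene of muscle, at -2.34 ± 0.17 (SE, n = 4). The others were LYNX1-SLURP2 (-2.31), the complement receptor gene C3AR1 (-2.27), the matrix gene EMILIN1 (-2.25), the urotensin receptor gene UTS2R (-2.19), the cardiac transcription factor gene NKX2-5 (-2.16), the pacemaker channel gene HCN2 (-2.11), the vasopressin gene AVP (-2.10), the globin gene CYGB (-2.08) and S100A5 (-2.08). All 12 were well above background in total RNA on all 8 arrays, and GNRH2 was so on 7 of 8 arrays in the immunoprecipitate. Relative to the median probe, their log2 total signals ranged from -1.23 (GNRH2) to 6.97 (NKX2-5), where GAPDH stood at 7.64. Each of the 12 was read by 1 kept probe, and whether these probes measured the named transcripts was not tested.

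Over all features, 4535 were higher and 4478 lower in the immunoprecipitate at an adjusted p under 0.05, and 7349 did not pass. The balance of the counts depends on the centring, since they were 4065 and 5132 without it. Even then the signals were dye-normalized on each array (median log2 ratio -0.07), so the balance before normalization is not shown. The counts were 3826 and 4999 with quantile normalization, a setting that also changes the background correction. Among the 3880 named genes, 1137 were higher, 1114 lower and 1629 did not pass. The upper tail was longer: 1911 features passed and were at least 2-fold higher, against 955 at least 2-fold lower, and 121 were at least 8-fold higher against 2 lower. Of the calls, 28 higher features were not well above background in total RNA on any array. For the lower features and the immunoprecipitate this held for 1. With both channels required to be well above background, 3968 were higher and 3976 lower of 14137, and the tails were not counted there. Of the calls, 3711 higher and 3632 lower features had the same sign on all 8 arrays. With the slide as a block the counts were 4384 higher and 4282 lower. They were 3984 and 3657 within slide 1 (L1236 and L428), and 1914 and 1392 within slide 2 (L540 and KM-H2).

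**Figure D1:**
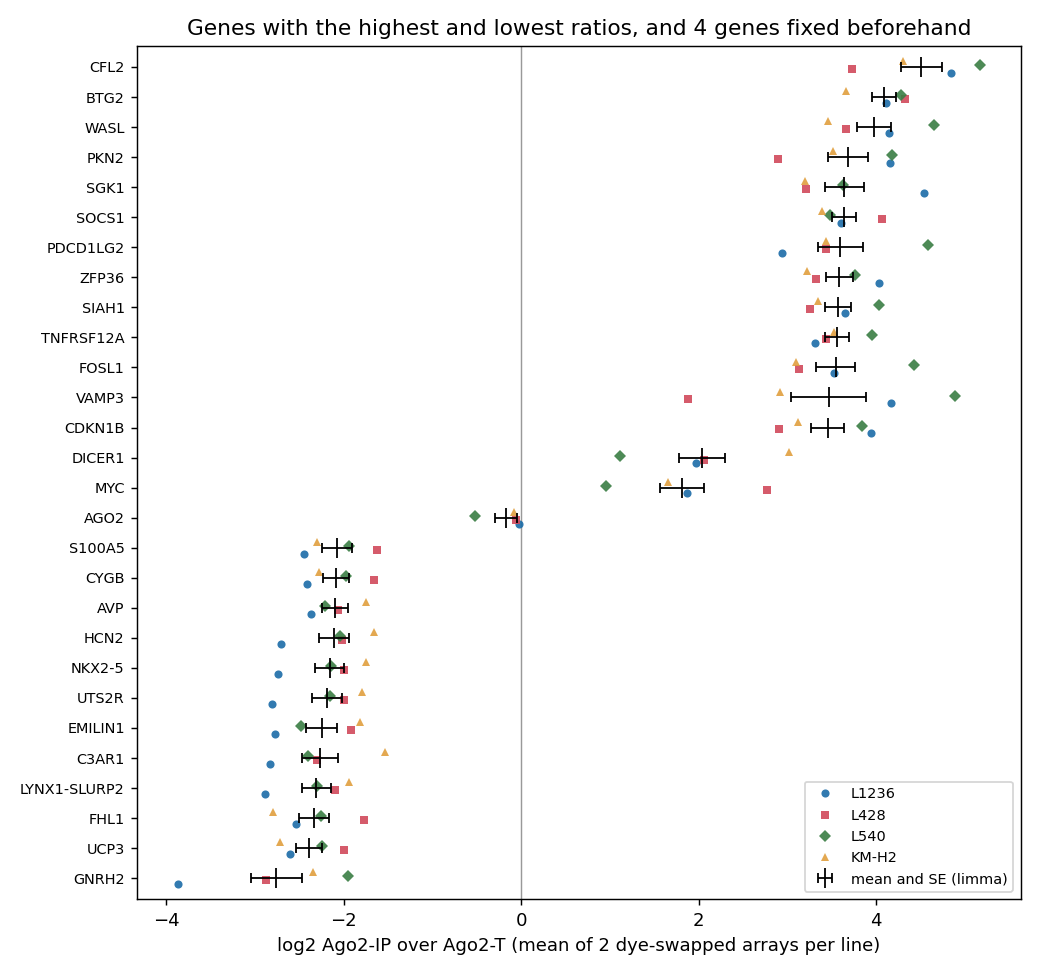
Log2 Ago2-IP over Ago2-T (horizontal axis) of the 12 highest and 12 lowest named genes and of CDKN1B, DICER1, MYC and AGO2 (vertical axis). Coloured symbols are the cell lines, each the mean of 2 dye-swapped arrays, and black bars are the mean of 4 lines with limma's SE. CFL2 is drawn highest at 4.51, with total signal above background on 2 of 8 arrays, and GNRH2 is lowest at -2.76, while AGO2 lies at -0.17.

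Of 22 measured published targets of miR-24-3p, 8 were higher in the immunoprecipitate, 3 were lower and 11 did not pass, and the counts adjusted over the list alone were also 8 and 3. The inhibitor of cyclin-dependent kinases CDKN1B led the list at 3.45 ± 0.19 (SE, n = 4, adjusted p = 1.94e-05), higher on all 8 arrays. MYC followed at 1.81 ± 0.25 (SE, n = 4, adjusted p = 0.000619), then CCNA2 at 1.73 ± 0.13, INSIG1 at 1.40 ± 0.15 and CDK1 at 1.13 ± 0.12 (SE, n = 4). The DNA repair gene BRCA1 (-0.70), FAF1 (-0.51), a mediator of apoptosis, and the replication helicase gene MCM4 (-0.48) were lower. The list median was 0.12, and the list was not separated from the other named genes (camera, adjusted p = 0.182, and adjusted p = 0.473 with an estimated correlation). From median intensities with normexp correction and no loess it was (camera, adjusted p = 0.0383, against 0.0383 to 0.473 over all settings run).

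**Figure D2:**
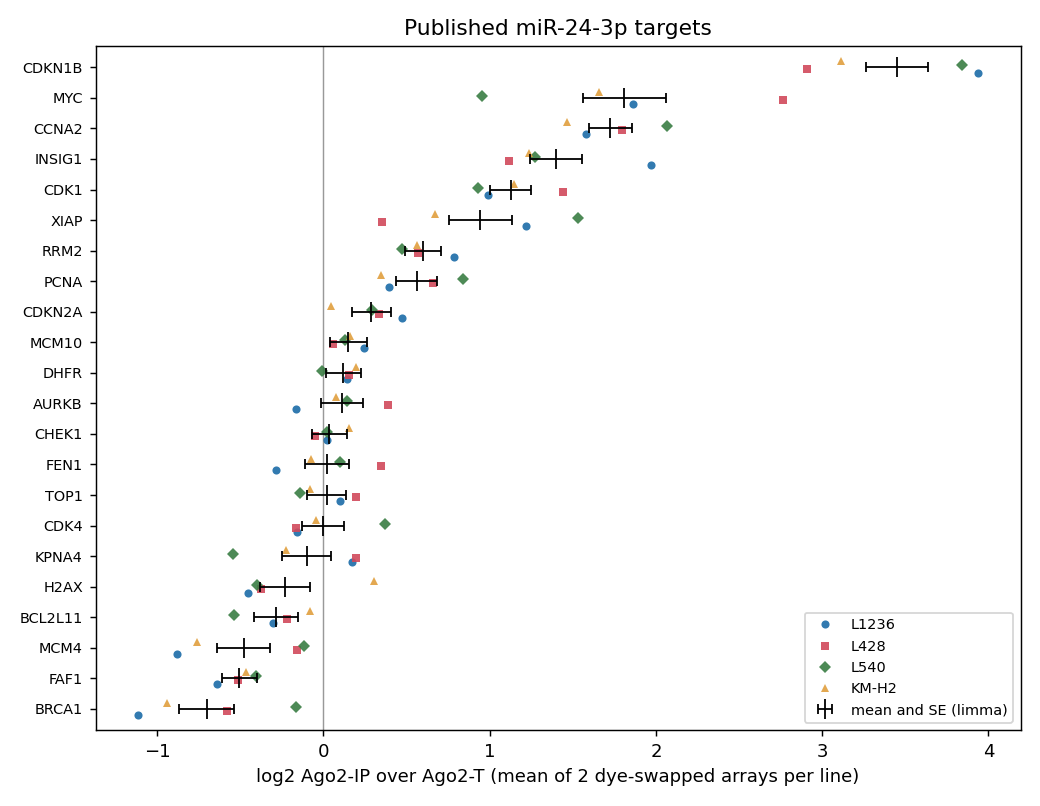
Log2 Ago2-IP over Ago2-T (horizontal axis) of the 22 measured published miR-24-3p targets (vertical axis). Coloured symbols are the cell lines, each the mean of 2 dye-swapped arrays, and black bars are the mean of 4 lines with limma's SE. CDKN1B stands apart at 3.45, and BRCA1 is lowest at -0.70.

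Published targets of the other microRNAs lay higher in the immunoprecipitate than named genes in general by camera with a preset correlation, and none of these 5 calls held with an estimated correlation (adjusted p = 0.343 to 0.473). For let-7, 16 of 21 measured targets were higher and 1, THBS1 (-0.55), was lower, with a median of 0.84, and CDC25A (2.07), IGF2BP3 (2.13) and PRDM1 (1.79) were among the higher ones. IMP3 (0.32) was counted as higher beside IGF2BP3, and whether it is a separate let-7 target was not checked. For miR-155-5p, 12 of 17 were higher and 0 lower (median 0.99), among them SOCS1 (3.64), the mitotic inhibitor kinase gene WEE1 (3.46 ± 0.17, SE, n = 4), BACH1 (2.88), TAB2 (2.28), JARID2 (2.24) and CEBPB (1.95). For miR-21-5p, 12 of 15 were higher and 0 lower (median 0.89), among them BTG2 (4.09), SKI (1.99) and RECK (1.91, total signal above background on 6 of 8 arrays). For microRNAs of the MIR17HG cluster, 13 of 21 were higher and 0 lower (median 0.63), among them E2F3 (2.42), CDKN1A (1.97), FBXW7 (1.96) and MAP3K8 (1.76). For miR-9-5p, 8 of 13 were higher and 0 lower (median 0.50), among them CXCR4 (1.26) and BCL6 (1.09). Camera gave adjusted p values of 0.000297 for let-7, 0.00134 for miR-155-5p, 0.00072 for miR-21-5p, 0.00462 for the MIR17HG cluster and 0.00985 for miR-9-5p. With an estimated correlation the adjusted p was 0.343, 0.473, 0.343, 0.343 and 0.343 in that order. The counts adjusted over each list alone were the same as those over all features. The 6 target lists together held 98 distinct measured genes, 11 of them in more than 1 list, and 62 were higher and 4 lower.

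Among genes of the silencing machinery, 6 of 17 were higher, 3 were lower and 8 did not pass (6 and 3 also when adjusted over the list alone). DICER1, which encodes the enzyme that cuts microRNA precursors, stood at 2.04 ± 0.26 (SE, n = 4, adjusted p = 0.000425), its partner gene TARBP2 at 1.02 ± 0.13 and the decapping enzyme gene DCP2 at 0.72 ± 0.14. FKBP4, a co-chaperone of HSP90, was lower at -0.78 ± 0.11 (SE, n = 4), as were SND1 (-0.68) and DGCR8 (-0.56), which encodes the partner of the nuclease DROSHA. The transcript of AGO2 itself did not pass, at -0.17 ± 0.13 (SE, n = 4, adjusted p = 0.267). The list as a whole was not separated from the other genes (camera, adjusted p = 0.605).

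Immediate early genes and genes with AU-rich messengers, whose transcripts are induced fast and decay fast, had the highest median of the lists. Of 33 measured, 28 were higher and 0 lower (30 and 0 adjusted over the list alone), with a median of 1.53 (camera, adjusted p = 1.94e-10). With an estimated correlation this call did not hold (camera, adjusted p = 0.162). The estimate itself was 0.0143, near the preset 0.01, so correlation among the members is argued against as the cause of the loss. Besides BTG2, SOCS1, SGK1 and ZFP36, the list held TRIB1 (3.28 ± 0.11, SE, n = 4) and the phosphatase gene DUSP2 (3.38 ± 0.14, SE, n = 4). BTG2, SOCS1, MYC and TNFAIP3 are also in the microRNA target lists, so the immediate early list is not fully separate from those. The list median was 1.67 on slide 1 and 1.59 on slide 2.

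Apoptosis genes were also higher as a list, with 17 of 31 higher and 4 lower (median 0.54, camera, adjusted p = 0.00586, and adjusted p = 0.473 with an estimated correlation). The higher members included inhibitors of cell death, BIRC3 (2.06 ± 0.16, SE, n = 4) and BCL2L2 (1.64 ± 0.15), as well as promoters of it, BBC3 (1.34 ± 0.13) and CASP8 (3.00), which encodes an initiator caspase. The lower members were BAD (-1.14 ± 0.11), DFFA (-0.63), FAF1 (-0.51) and CASP10 (-0.39). Of genes known to mark Hodgkin and Reed-Sternberg cells, 16 of 34 were higher and 5 lower (median 0.35, camera, adjusted p = 0.0469, and adjusted p = 0.343 with an estimated correlation). The higher ones included the genes of both PD-1 ligands, PDCD1LG2 (3.60, total signal above background on 3 of 8 arrays) and CD274 (3.30 ± 0.18, SE, n = 4, total signal above background on 6 of 8 arrays), as well as NFKBIA (1.39 ± 0.12). The lower ones were STAT5A (-0.98), CCL17 (-0.83), CCL5 (-0.55), RELB (-0.42) and TNFRSF8 (-0.28). This list did not pass with the slide as a block (adjusted p = 0.0541), without L540 (0.0584) or without KM-H2 (0.0526). Of cell cycle genes, 17 of 43 were higher and 4 lower (median 0.21, camera, adjusted p = 0.0191, and adjusted p = 0.506 with an estimated correlation), and without L540 the adjusted p was 0.0573. WEE1, CDKN1B, E2F3 and CCNE1 (2.27 ± 0.16, SE, n = 4) had the lowest p, and the lower members were MCM4 (-0.48), CDC20 (-0.43), MCM6 (-0.42) and TK1 (-0.41). The counts of these 3 lists were the same when adjusted over the list alone.

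Replication dependent histone transcripts, which end in a stem-loop and not in a poly(A) tail, were lower in the immunoprecipitate. Of 16 measured, 10 were lower and 0 higher, also when adjusted over the list alone, with a median of -0.83 (camera, adjusted p = 0.00072, and adjusted p = 0.54 with an estimated correlation). H3C15 (-1.82 ± 0.20) and H2AC20 (-1.82 ± 0.17) were the lowest (SE, n = 4), and near-identical histone genes can share a probe's signal. The list median was -1.01 on slide 1 and -0.59 on slide 2. The list of nuclear encoded subunits of the respiratory chain also lay lower, with a median of -0.36 (camera, adjusted p = 0.0363, and adjusted p = 0.712 with an estimated correlation). Of 27 measured, 13 were lower, 2 were higher, UQCRB (0.88) and NDUFV2 (0.52), and 12 did not pass. The counts of 13 and 2 were the same when adjusted over the list alone. COX4I1 (-1.20 ± 0.11) and ATP5F1D (-1.16 ± 0.13) were the lowest (SE, n = 4), and without L1236 the list's adjusted p was 0.0758. Ribosomal protein transcripts went both ways, with 14 of 28 lower, such as RPLP2 (-1.19 ± 0.10, SE, n = 4), and 7 higher, such as RPL22 (2.16 ± 0.16, SE, n = 4), also over the list alone. That list did not pass (median -0.28, camera, adjusted p = 0.22) except from median intensities with normexp correction and no loess (adjusted p = 0.00109).

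**Figure D3:**
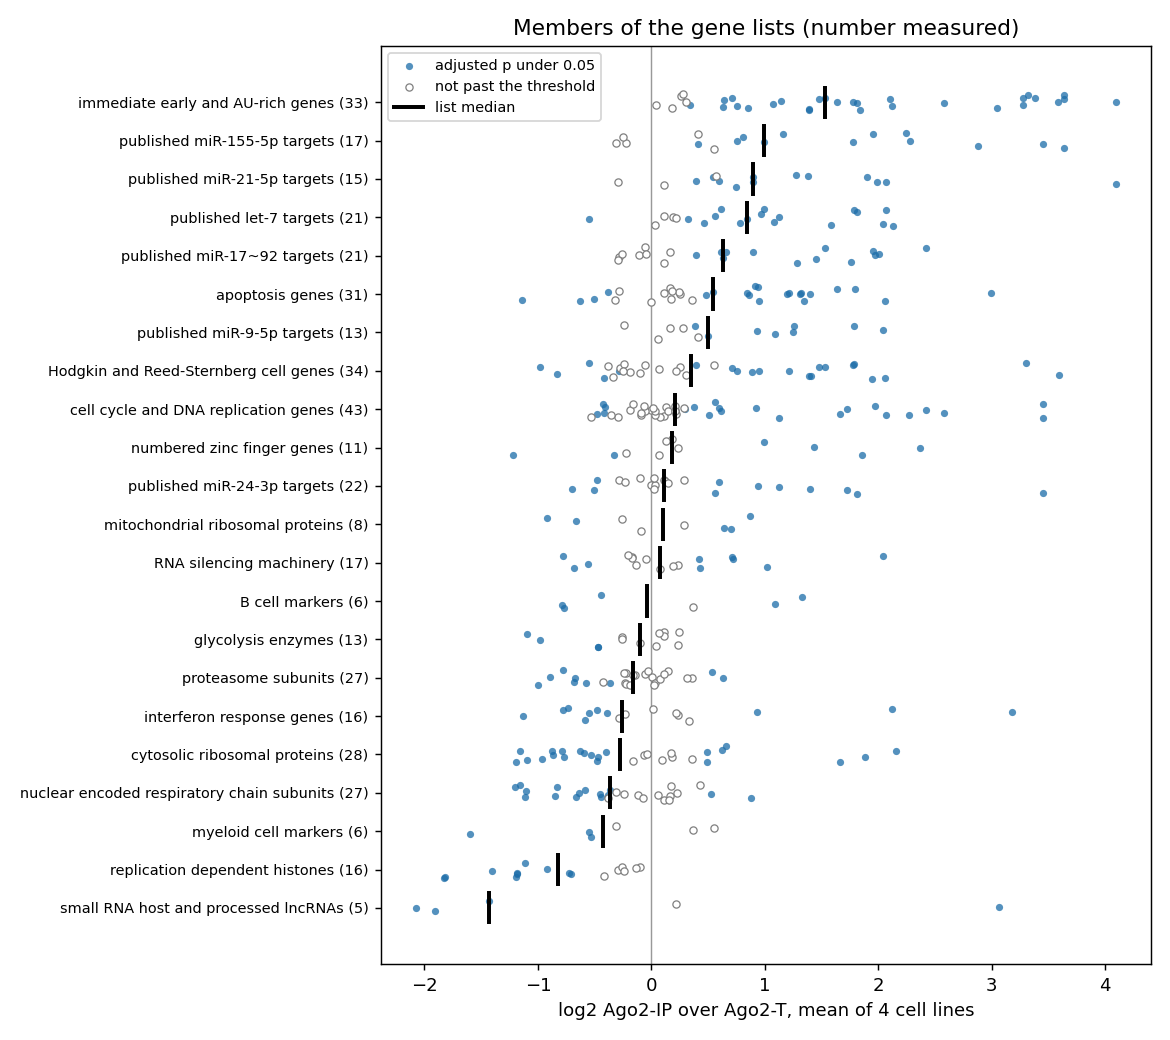
Log2 Ago2-IP over Ago2-T (horizontal axis, mean of 4 cell lines) of the members of each gene list (vertical axis, with the number measured). Filled points passed an adjusted p under 0.05, open points did not, and black bars are list medians, from 1.53 for immediate early and AU-rich genes to -1.43 for the 5 small RNA host and processed RNAs, of which H19 lies at 3.07.

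The remaining lists were not separated from the other named genes by camera. Of 27 proteasome subunits 2 were higher, PSMB4 (0.64) and PSMB1 (0.53), and 7 lower, or 6 lower when adjusted over the list alone (median -0.16, adjusted p = 0.219, and 0.0444 without L540), with PSMB2 at -0.90 and PSMA7 at -0.78. The median of this list turned to 0.01 with normexp correction and no loess, and was -0.18 with normexp correction and loess. Of 13 glycolysis enzymes 0 were higher and 4 lower, or 2 lower over the list alone (adjusted p = 0.372), with PFKL at -1.10, GAPDH at -0.98 and GPI and HK1 at -0.47. Interferon response genes had 3 of 16 higher, IRF9 at 3.18, IRF1 at 2.12 and OAS2 at 0.93, and 7 lower, such as ISG15 at -1.13 (adjusted p = 0.549), so that the median (-0.26) and the mean (0.12) differed in sign. Of 11 numbered zinc finger genes 4 were higher and 2 lower (adjusted p = 0.315), with ZNF217 highest at 2.37 and ZNF587 lowest at -1.22. Of 8 mitochondrial ribosomal protein genes 3 were higher and 2 lower, or 4 and 3 over the list alone (adjusted p = 0.86), with MRPL19 highest at 0.87 and MRPS15 lowest at -0.92.

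Few non-coding RNAs could be named. H19 was higher, at 3.07 ± 0.27 (SE, n = 4, adjusted p = 7.24e-05), though its total signal was above background on 4 of 8 arrays. LINC00467 (0.23), MIR155HG (0.22), the host transcript of miR-155, and PVT1 (-0.15) did not pass. The non-coding RNAs RN7SK (-2.07 ± 0.24), RMRP (-1.91 ± 0.15) and TERC (-1.43 ± 0.17) were lower (SE, n = 4). The list of small RNA host and processed RNAs, with these 3, H19 and MIR155HG, had 1 higher and 3 lower (camera, adjusted p = 0.365). PVT1 was the single measured member of the nuclear retained list and LINC00467 of the long intergenic list, and no mitochondrially encoded gene was measured. The median of the 4 long non-coding RNAs minus that of 3868 protein-coding genes was on average 0.27 (SD 0.21, n = 4 lines, exact two-sided sign permutation p = 0.25, a test in which 4 lines cannot reach a p under 0.05). The 7 named non-coding RNAs as a set had a median of -0.15 (camera, p = 0.394, and p = 0.65 with an estimated correlation).

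By cell line, features at least 2-fold higher on both arrays numbered 1975 in L1236, 1442 in L428, 1813 in L540 and 1322 in KM-H2, and those at least 2-fold lower numbered 1218, 608, 732 and 755. Shared by all 4 lines were 690 higher and 343 lower features, where independent lists of these sizes would share 1.56 and 0.0934. All lines were read by the same probes, without a mock immunoprecipitate. The excess therefore does not tell binding to Ago2 from effects of probes or of unspecific recovery. From median intensities with normexp correction and no loess, 441 and 189 were shared. The arrays of a line share both fractions and no test applies to a single line. Pearson correlations of the ratios across features, which are not independent replicates, ranged from 0.79 (L540 with KM-H2, Spearman 0.746) to 0.886 (L1236 with L428, Spearman 0.864), both pairs on 1 slide. Pairs on different slides ranged from 0.83 to 0.869. Only 2 features were at least 2-fold higher on both arrays of 1 line and at least 2-fold lower on both of another, H4C16, a histone gene, and an unnamed probe, both named because of these values.

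In total RNA, Hodgkin and Reed-Sternberg genes were well above background on both arrays for 38 of 41 in L1236, 36 in L428, 34 in L540 and 36 in KM-H2. B cell markers were detected at 10, 8, 6 and 10 of 17 in the same order, T cell markers at 6, 6, 6 and 11 of 20, and myeloid markers at 6, 6, 6 and 8 of 17. KM-H2 was the line with the most T cell markers, where the total signals of CD3D and ZAP70, genes of T cell receptor signalling, lay 3.26 and 1.59 above the median probe on the log2 scale. ZAP70 was not well above background on any array of the other lines, and CD3D was so on 1 of 2 arrays in L1236 and in L540 and on 0 in L428. Other T cell markers, such as CD3E, CD247 and LCK, were not well above background on any array of KM-H2, and CD247 was so on both arrays of L540. All these genes were singled out after their values were seen, and a single line has no replicate. In the ratio, B cell markers had 2 of 6 higher (EBF1 at 1.33, with total signal above background on 6 of 8 arrays, and BCL6 at 1.09) and 3 lower (CD79A at -0.79, BLK at -0.77 and CD37 at -0.45). Myeloid markers had 0 of 6 higher and 3 lower (TYROBP at -1.60, CSF3R at -0.55 and FCER1G at -0.53). Camera gave an adjusted p of 0.905 for B cell and 0.311 for myeloid markers. Of 4 measured T cell markers 2 were higher (SH2D1A at 0.59, GATA3 at 0.40) and 1 lower (CD4 at -0.63), too few for a list test.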

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

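Chosen only after the results were seen were the test of the slides against the spike-in signal and the comparison of custom with catalogue features by share, which was taken up after the shares over all lines were known. Before that, 2 tests had been planned for a difference in medians, and they were dropped unrun once the medians were seen to differ by -0.03, with both signs among the 4 lines. A difference in medians stays open, since 4 lines cannot reach a p under 0.05 in the exact sign permutation (p = 0.5). Splitting the 8 extracts into other groups of 4 showed how far the counts depend on the grouping. Without pairing, the real split gave 874 calls and the highest of the other splits 420, and 1 of the 35 splits, the real one, gave as many. Chance can be excluded for that count only if fractions are exchangeable between lines, which ignores the pairing of the fractions by line. The 420 came from the split by slide (L1236 and L428 against L540 and KM-H2), which parts 0 of the pairs and keeps both fractions of a line together. The 8 splits that part all 4 pairs gave at most 0 calls besides the real one and are too few for a share under 0.05. With pairing there are 8 sign patterns of the lines, likewise too few: the real one gave 9013 calls, the highest other 0, and 1 pattern reached the real count.

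Of 33 immediate early and AU-rich transcripts, 28 were higher in the immunoprecipitate and 5 did not pass, and the call of the list was lost with an estimated correlation (adjusted p = 0.162). Dim total signal as the whole cause is argued against by the 29 members well above background in both channels on all 8 arrays, whose median was 1.437, above the 95th percentile (0.209) of 10000 random gene lists matched on total signal. Dye bias is argued against by the median of 1.47 in the lower dye orientation (1.64 in the other), and a slide effect by the lower slide median of 1.588. No biological explanation was tested, since the design has no group for it.

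Custom features, whose targets are unnamed here, were higher in the immunoprecipitate in 17.0% of 3528 cases against 30.7% of 12834 catalogue features, while 26.2% and 27.7% were lower and the medians differed by -0.03. The filter on dim probes kept 12.4% of custom and 43.5% of catalogue probes, so the custom features are the more selected set. In L1236, 4.88% of custom and 14.0% of catalogue features were at least 2-fold higher on both arrays, in KM-H2 3.03% and 9.47%. Custom features were dimmer (median log2 signal 8.57 against 10.1). Matched on mean signal, the smallest of the 4 line differences was 6.17 percentage points (L428), against 5.74 unmatched, which argues against dim signal as the whole cause. The smallest difference on an array was 5.94 points in the same direction on all 8 arrays, which argues against dye bias. The targets of the custom probes are not given in the sources used here. The design names long non-coding RNAs besides messengers, so the contrast could be one of these classes, which stays open, and no biological explanation was tested.

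Spike-in RNA, not used in any comparison, gave a median processed signal of 4970 on slide 1, where the negative controls had medians from 8.85 to 13.1 per channel. Every array of slide 1 had a lower spike-in median in Ago2-IP than in Ago2-T. The values went from 2438 against 9467 (L1236, IP in Cy3) to 4165 against 5780 (L428, IP in Cy5). What this means for centring at the median probe was not tested. On slide 2 the spike-in RNA gave 12.2 against 9 at negative controls. The correlation of observed with nominal spike-in level was 0.983 to 0.991 on slide 1 and 0.0848 to 0.227 on slide 2. If slides set the ratios, lines of a slide should correlate best, but the lower within-slide correlation was 0.79, under all 4 between-slide values (0.83 to 0.869). Slide 1 held the highest correlation of all (0.886), so a slide effect confined to slide 1 stays open.

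Of 132 values checked over the 4 lines, 8 had a line far from the others, where chance gives about 1 in 20. L540 lay apart for AGO2 (-0.52, others -0.09 to -0.03) and ARID3A (0.86, others 1.82 to 1.84). L428 lay apart for CDC25A (2.98, others 1.71 to 1.82) and for the median of miR-24-3p targets (0.264, others 0.137 to 0.156). L1236 lay apart for FKBP4 (-0.98, others -0.73 to -0.71) and for TERC (-2.06, others -1.28 to -1.16), which is itself the median of the small RNA host list (-2.06). KM-H2 lay apart for H19 (4.22, others 2.51 to 2.79), whose total signal was above background on 4 of 8 arrays, so the size of this gap is uncertain.

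Among the genes named by the rule, the lists tested and the features at least 2-fold changed in opposite ways, 3 had both arrays of a line above 0 and both arrays of another line below 0. The difference was not tested. H4C16 was 1.12 in L540 and -1.17 in L428. The unnamed probe A_33_P3214803 was 1.32 in L1236 and -1.26 in L540. For glycolysis enzymes, the list median averaged over the 2 arrays of a line was 0.087 in L540 and -0.36 in L1236. Taken over the line means of its members, the median was 0.09 in L540 and -0.23 in L1236, and KM-H2 was lowest at -0.35.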

How the results depend on the processing

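The slide block and the background of the list tests and the comparison of custom with catalogue features were added after seeing the data. No call reversed under any alternative run. Among lists not called, the median of proteasome subunits turned to 0.01 with normexp and no loess (-0.18 with normexp and loess). The camera direction of B cell markers, also not called, turned from down to up without L540. Among scalings, the lowest median of all features was -0.07. Without the filter on dim probes, 3579 were higher and 3737 lower, but of 57781 features and not of 16362, so a smaller share was called. As numbers, the counts of 4535 higher and 4478 lower stayed within 1.5 times of these values under the alternatives run, except for the 3 that follow. With no replicate block, as unpaired channels, 487 and 387 passed, all of them also called in the paired fit. Within slide 2 they were 1914 and 1392, and within slide 1, also 2 lines, 3984 and 3657, and the cause was not tested. Testing against a fold of 1.5 gave 1619 and 917. Features changed in all 4 lines numbered 1442 higher and 868 lower at 1.5-fold, 278 and 32 at 3-fold, and 441 and 189 with normexp and no loess, where the cause was not tested. With an estimated correlation the adjusted p of the lists rose to 0.343 (the MIR17HG cluster, let-7, miR-21-5p, miR-9-5p, Hodgkin and Reed-Sternberg genes) and 0.473 (miR-155-5p, apoptosis). It rose to 0.506 (cell cycle), 0.162 (immediate early), 0.712 (respiratory chain) and 0.54 (histones). That setting uses only the 3 residual degrees of freedom, which raises p whatever the correlation. How much of each rise came from correlation was not tested. The estimate was 0.0143 for immediate early genes, near the preset 0.01, and lower for miR-9-5p (-0.0571) and Hodgkin and Reed-Sternberg genes (-0.0178). For these lists correlation among members is argued against as the cause. For the other lists named here the estimates ranged from 0.0441 (the MIR17HG cluster) to 0.553 (histones). With normexp and no loess, miR-24-3p targets (0.0383) and ribosomal proteins (0.00109) passed. That setting changes the background correction and the dye normalization together, no list test was run with normexp and loess, and the cause was not tested. With the slide as a block the Hodgkin and Reed-Sternberg list did not (0.0541). Leaving out a line in turn, the adjusted p ranged from 0.0357 to 0.0584 for that list, from 0.00622 to 0.0573 for cell cycle genes, from 0.0177 to 0.0758 for the respiratory chain and from 0.0444 to 0.352 for the proteasome. Custom minus catalogue features differed by -0.0309, against 0.27 for long non-coding minus coding. Of the named genes, 65 lost their call without pairing, 22 against a fold of 1.5 and 18 within slide 2. Signals over background limit the ratios of dim genes: in the filter on both channels 14137 features remained. The test of sites in untranslated regions and its 4 alternatives were not run.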

Other observations

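Named genes were also grouped by the letters before the digits of their symbol, a test set before its result was seen, and 40 roots with at least 8 measured members were tested with camera. The hypothesis that families move together was met for 1 root, DUSP, the dual-specificity phosphatases, many of which switch off MAP kinases (adjusted p = 0.0441, and adjusted p = 0.943 with an estimated correlation). Of its 8 measured members 6 were higher, DUSP2 (3.38), DUSP5 (3.27), DUSP1 (2.10), DUSP10 (1.23), DUSP6 (1.07) and DUSP12 (0.78), and DUSP3 (0.18) and DUSP4 (-0.03) did not pass. DUSP1, DUSP2, DUSP5 and DUSP6 also belong to the immediate early list and DUSP12 to the let-7 list. RNF, a root of RING finger genes, had 6 of 8 members higher and 0 lower but did not pass (median 1.23, adjusted p = 0.0913, and adjusted p = 0.943 with an estimated correlation).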
